A study of Homo sapiens with 60 samples.

How the data were processed

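RNA was measured by sequencing in SW1783 human astrocytoma cells treated for 24 h with water extracts of herbal medicines or with vehicle, per the labels. The sample labels give the vehicle as 0.1% DMSO and the series text as 2% DMSO. Per the labels' protocols, libraries came from total RNA with a directional kit (MGIEasy) and were read as 100 bp pairs on an MGIseq instrument, and samples with too little RNA were left out. Per the submitters' processing notes, FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 were used with hg38. The annotation release and the strand setting of the counting are not given in the sources used here. The series text also speaks of a wortmannin control and ethanol extracts, which are not analysed here.

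The authors deposited RSEM expected counts per gene, 60675 Ensembl gene IDs in 60 libraries, and 10.9% of the values were not whole numbers. These were rounded. Symbols came from a table of gene names, which listed 56558 IDs, some of them with no symbol but the ID, and else from GENCODE 29, which gave positions on hg38. IDs left without a symbol number 18969 and held 0.397% of counts. In every library 1 CPM stands for 18.7 or more counts. Replicates differed by 1.56 to 78.9 times the sampling noise, and no library was counted as a repeat of another.

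Groups follow the labels: vehicle and 6 extracts at 500, 100 and 20 µg/mL with 3 libraries each, 57 libraries in 19 groups. Soshiho-tang, with 1 library per dose, entered no test. Genes were kept with edgeR's filterByExpr (17412 kept), scaled by TMM (factors 0.934 to 1.10) and fitted with edgeR 4.0.16 by 1 quasi-likelihood model with a mean per group, at a common biological coefficient of variation of 0.104. Standard errors are the log2 fold change divided by the square root of F. Comparisons were the 18 groups against vehicle, 500 against 20 µg/mL of each of the 6 extracts and 5 pairs of extracts at 500 µg/mL, 29 in all. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison.

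The 33 gene lists were tested with limma 3.58.1 (camera with a preset correlation of 0.01, camera with an estimated correlation, and fry), adjusted over the 33 lists of a comparison. They were AhR targets, NRF2 targets, metallothioneins and zinc export, unfolded protein response chaperones, ATF4 targets, p53 targets, mitosis genes, DNA replication genes, cholesterol synthesis and uptake, fatty acid synthesis, LXR targets, NF-kB and inflammatory genes, interferon-stimulated genes, hypoxia genes, glycolysis enzymes, heat shock genes, extracellular matrix genes, TGF-beta and YAP targets, glucocorticoid-induced genes, immediate early and MAPK output genes, FOXO targets, lysosome and autophagy genes, iron handling genes, astrocyte and glioma markers, nuclear oxidative phosphorylation genes, oxidative phosphorylation genes of mitochondrial DNA, ribosomal protein genes, replication-dependent histones, neuron markers, myeloid markers, endothelial markers, oligodendrocyte markers and epithelial markers. For Soshiho-tang, log2 ratios to the vehicle mean used a pseudocount of 1 CPM, and list medians were ranked among 10000 random lists of the same size matched on expression.

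Named genes follow a rule. For 500 µg/mL against vehicle these are the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 5 CPM in 1 group, all 3 treated libraries on 1 side of the other 3, and a symbol that is no clone or locus name, and up to 4 members with the lowest adjusted p of each list that camera called. The lower doses take 3 and 3, the other comparisons 5 and 5, and Soshiho-tang the 5 highest and 5 lowest at 500 µg/mL. Genes changed the same way by all 6 extracts are the 10 with the largest smallest fold. Some genes that this rule would name are not reported here. The gene lists, groups, comparisons, this rule and the alternatives named next were chosen before the data were examined.

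Those alternatives were RLE scaling, no filter, DESeq2 1.42.0, only the 6 libraries compared, the replicate number as a block and leaving out each library in turn, for lists an estimated correlation and fry, and for correlations Spearman's rho and the 9737 genes with a mean of at least 10 CPM. Added after seeing the data were a term for early (31) and late (26) libraries by library name, removal of the trend of each library with transcript length, the fit without the deviant library, that fit with the batch term, and early or late libraries alone. The length score compares transcripts under 1702 bp with those over 5524.6 bp, the lowest and highest 20% of genes. Shared vehicle libraries were handled with 8 simulations of unchanged groups without batches. The test was tested on simulated data, where 10 unchanged genes of 16947 were called, and a changed list but 0 of 32 unchanged lists was called. R 4.3.3, the R package data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9 were used.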

Results

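SW1783 cells, a human astrocytoma line, were treated for 24 h with water extracts of 2 single herbs and 5 mixed prescriptions, and RNA was sequenced in 60 libraries. Vehicle (DMSO) and 18 extract-by-dose groups held 3 libraries each: Menthae Herba (mint herb), Saposhnikoviae Radix (root of Saposhnikovia), Saengmaek-san, Guibi-tang, Soyo-san and Okbyeongpung-san, each at 500, 100 and 20 µg/mL. Soshiho-tang had 1 library at each of these doses and is described with the other observations. Total counts per library, in units of 1e6, ran from 18.7 to 33.4 with a median of 24.5. Of 60675 gene IDs, 17412 passed the expression filter and were tested. Gene values are log2 fold changes±SE with n = 3 libraries per group, levels are mean CPM±SD (counts scaled to a total of 1e6), and positions are on hg38. The labels do not say whether replicates were separate cultures, so each p measures the spread between these libraries.

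Against vehicle at 500 µg/mL, edgeR's quasi-likelihood test called 6137 genes with Guibi-tang, 2170 with Soyo-san, 1259 with Okbyeongpung-san, 1197 with Saengmaek-san, 433 with Menthae Herba and 29 with Saposhnikoviae Radix at a Benjamini-Hochberg adjusted p under 0.05. Saengmaek-san and Guibi-tang libraries fell into an early and a late part of the library order. Those of Soyo-san and Okbyeongpung-san were all late and those of Menthae Herba and Saposhnikoviae Radix all early. Vehicle, a set of its own by name, was taken as early, and against it library set and treatment cannot be separated. The place of the division was found in the same data, where late libraries held a lower share of long transcripts.

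**Figure D1:**
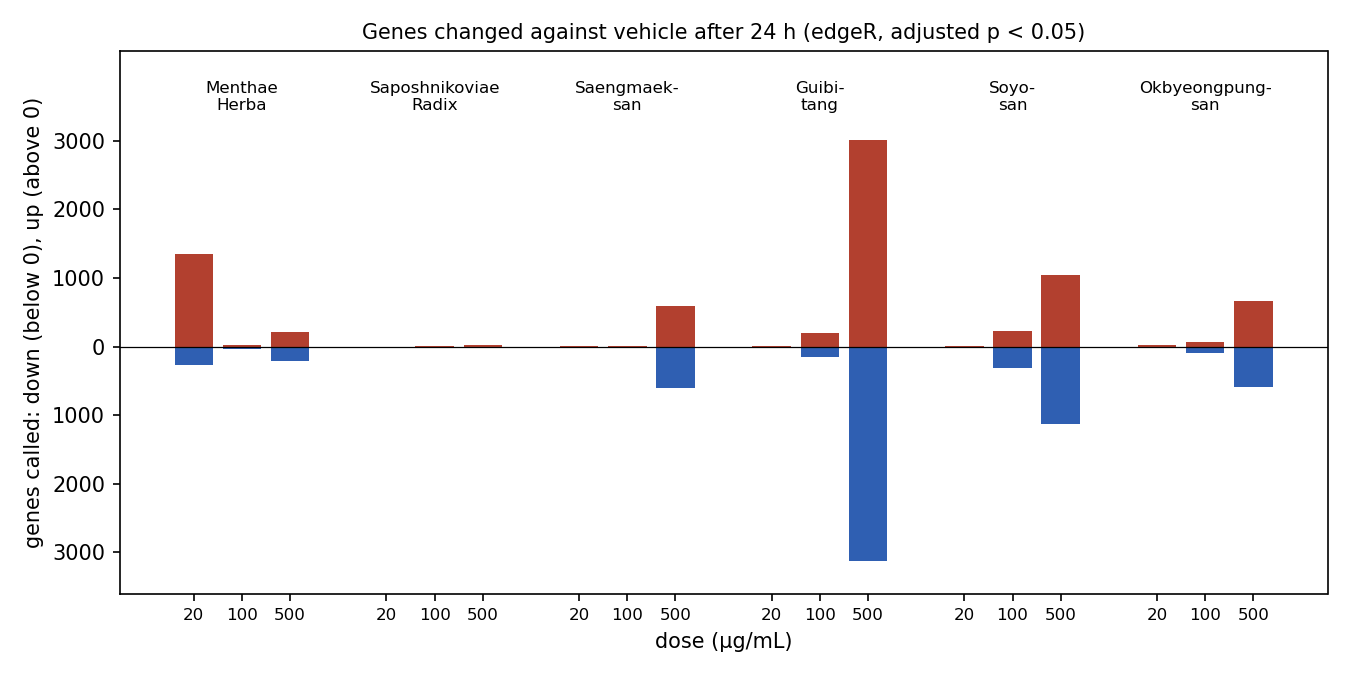
Genes called higher (red, above 0) and lower (blue, below 0) against vehicle by edgeR at each dose in µg/mL, with 3 libraries per group. Guibi-tang at 500 µg/mL has the tallest bars, 3007 up and 3130 down, and the Menthae Herba bars at 20 µg/mL fall to 0 without its replicate 2.

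With Menthae Herba at 500 µg/mL hypoxia genes rose together against vehicle: 20 of 27 rose, 0 fell and 7 were not called, with 25 up adjusted over the list alone and a median of 0.47 (camera adjusted p = 1.03e-54, adjusted p = 6.85e-18 with an estimated correlation). NDRG1, a hypoxia-induced stress gene (ENSG00000104419, chromosome 8, 133237171 to 133302022, minus strand), went from 56.3±0.935 CPM to 136±2.25 CPM (1.28±0.11, edgeR adjusted p = 8.8e-12). The mitophagy receptor BNIP3L rose by 0.61±0.07, the aldolase ALDOC by 0.98±0.12 and the glucose transporter SLC2A1 by 0.46±0.06. Among the highest folds were APLN, which encodes the peptide apelin (1.57±0.14, edgeR adjusted p = 3.5e-11), the miR-210 host MIR210HG (1.41±0.20) and TXNIP, a glucose-responsive arrestin (1.35±0.10). They were followed by FER1L4 (1.16±0.20), the lipase inhibitor ANGPTL4 (1.15±0.17), FGF11 (1.09±0.12) and IGFBP1 (1.08±0.16). The lowest were the long non-coding RNA UCA1 (-1.58±0.16, edgeR adjusted p = 3.4e-09), ANKRD1 (-1.57±0.19), the vitamin D hydroxylase CYP24A1 (-1.38±0.11) and PADI2 (-1.30±0.16). Next came LGR6 (-1.17±0.18), KCNA7 (-1.10±0.28) and SAMD11 (-1.08±0.10).

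Amino-acid response genes under ATF4 moved up (8 up and 0 down of 25, 17 and 0 adjusted over the list alone, camera adjusted p = 6.64e-14, adjusted p = 0.000443 with an estimated correlation). VLDLR stood at 0.56±0.08, STC2 at 0.41±0.08 and ASNS, asparagine synthetase, at 0.34±0.09. Glycolysis enzymes (3 up and 0 down of 11, 6 and 0 adjusted over the list alone, camera adjusted p = 3.37e-08, adjusted p = 0.010 with an estimated correlation) included PFKP (0.30±0.05) and GAPDH (0.47±0.09). NRF2 targets (4 up and 0 down of 29, 16 and 0 adjusted over the list alone, camera adjusted p = 1.17e-11, adjusted p = 0.0103 with an estimated correlation) included the cystine carrier SLC7A11 (0.57±0.12) and HMOX1 (0.60±0.14). Targets of the aryl hydrocarbon receptor (AhR) (2 up and 0 down of 8, 5 and 0 adjusted over the list alone, camera adjusted p = 1.99e-05, adjusted p = 0.0309 with an estimated correlation) included ALDH3A1 (1.48±0.28). TGF-beta and YAP targets (0 up and 4 down of 13, 0 and 5 adjusted over the list alone, camera adjusted p = 6.01e-07, adjusted p = 0.0297 with an estimated correlation) moved down with ACTA2 (-0.35±0.09). Heat shock genes (0 up and 3 down of 18, 0 and 6 adjusted over the list alone, camera adjusted p = 7.13e-05, adjusted p = 0.0297 with an estimated correlation) moved down with HSPH1 (-0.24±0.06). DNA replication genes (0 up and 1 down of 31, 0 and 6 adjusted over the list alone, camera adjusted p = 1.74e-05, adjusted p = 0.0317 with an estimated correlation) did so with MCM6 (-0.21±0.06).

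Called up by camera as lists, though not with an estimated correlation, were FOXO targets (3 up and 0 down of 13, 3 and 1 adjusted over the list alone), replication-dependent histones (0 and 0 of 11, then 0 and 0), mitosis genes (0 and 0 of 30, then 0 and 0) and interferon-stimulated genes (0 and 0 of 26, then 0 and 0). Called down were metallothioneins and zinc export (0 up and 1 down of 5, 0 and 1 adjusted over the list alone), unfolded protein response chaperones (0 and 1 of 18, then 0 and 2) and epithelial markers (0 and 2 of 5, then 1 and 2). These 7 had camera adjusted p between 0.00227 and 0.0424, and adjusted p between 0.0768 and 0.525 with an estimated correlation.

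edgeR called 433 genes, 216 up and 217 down, of which 27 rose and 19 fell at least 2-fold. Without vehicle replicates 1, 2 and 3 in turn the count was 277, 261 and 233, and without Menthae Herba replicates 1, 2 and 3 it was 242, 285 and 236. It was 937 when Menthae Herba 20 µg/mL replicate 2, a library that stood apart and is called the deviant library here, left the fit.

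Saposhnikoviae Radix at 500 µg/mL, the other single herb, changed few genes. CXCL8, the neutrophil chemokine interleukin 8 (ENSG00000169429, chromosome 4, 73740506 to 73743716, plus strand), went from 3.07±0.583 CPM to 6.29±0.959 CPM (1.04±0.22, edgeR adjusted p = 0.0266). TXNIP rose by 0.82±0.10. The other highest named genes were MIR100HG (0.55±0.08), PRDM8 (0.52±0.11), the matricellular gene CCN1 (0.51±0.09), the lymphatic growth factor VEGFC (0.41±0.07), DMRTA2 (0.39±0.08) and DIRAS3 (0.38±0.08). The endoplasmic reticulum chaperone HSPA5 (ENSG00000044574, chromosome 9, 125234853 to 125241330, minus strand) went from 3242±44.6 CPM to 2479±68.9 CPM (-0.39±0.07, edgeR adjusted p = 0.00203). Its partners HERPUD1 (-0.35±0.07) and PDIA4 (-0.25±0.05) fell too. Also lower were the phosphatase DUSP10 (-0.40±0.08), STX3 (-0.32±0.07), FBXO32 (-0.30±0.07) and the plasminogen activator PLAT (-0.27±0.05). Unfolded protein response chaperones moved down as a list (0 up and 3 down of 18, 0 and 5 adjusted over the list alone, median -0.17, camera adjusted p = 2.40e-10, adjusted p = 4.68e-05 with an estimated correlation).

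Hypoxia genes, which rose with Menthae Herba, moved down here with 0 members called over all genes (0 up and 0 down of 27, 0 and 10 adjusted over the list alone, median -0.16, camera adjusted p = 1.32e-12, adjusted p = 2.43e-08 with an estimated correlation). AhR targets, with ALDH1A3 at 0.32±0.05, and other small list shifts also held with an estimated correlation. Up were AhR targets (1 up and 0 down of 8, 2 and 0 adjusted over the list alone), mitosis genes (0 and 0 of 30, then 2 and 0) and replication-dependent histones (0 and 0 of 11, then 1 and 0). Down were metallothioneins and zinc export (0 up and 0 down of 5, 0 and 0 adjusted over the list alone), cholesterol synthesis and uptake (0 and 0 of 24, then 0 and 0) and lysosome and autophagy genes (0 and 0 of 23, then 0 and 1). All 6 had camera adjusted p between 1.69e-08 and 0.00179, and adjusted p between 0.00466 and 0.0484 with an estimated correlation. Not held were NF-kB and inflammatory genes (1 up and 0 down of 30, 4 and 0 adjusted over the list alone), glucocorticoid-induced genes (1 and 0 of 8, then 1 and 0), NRF2 targets (0 and 0 of 29, then 1 and 0) and immediate early and MAPK output genes (0 and 0 of 23, then 1 and 0), up with CXCL8 and SGK1 (0.32±0.07) among them. Down and not held were ATF4 targets (0 up and 0 down of 25, 1 and 2 adjusted over the list alone), fatty acid synthesis (0 and 0 of 13, then 0 and 1) and extracellular matrix genes (0 and 0 of 26, then 0 and 0). Those 7 had camera adjusted p between 0.000189 and 0.0338, and adjusted p between 0.0865 and 0.387 with an estimated correlation.

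edgeR called 29 genes, 19 up and 10 down, with 1141 genes at an unadjusted p under 0.05 and 28 up and 20 down by DESeq2. The count was 8, 10 and 8 without vehicle replicates 1, 2 and 3, and 10, 10 and 9 without the extract's replicates 1, 2 and 3. It was 97 without the deviant library and 61 with the length trend removed.

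Saengmaek-san at 500 µg/mL, a mixed prescription, was compared with vehicle. TXNIP (ENSG00000265972, chromosome 1, 145992435 to 145996600, minus strand) went from 9.78±0.624 CPM to 88.4±10.7 CPM (3.18±0.10, edgeR adjusted p = 6.7e-27). Its paralogue ARRDC4, also glucose-responsive, rose by 1.37±0.12. CXCL8 rose by 1.74±0.21, the cytokine IL1B by 0.85±0.16, the hair keratin-associated gene KRTAP2-3 by 1.94±0.27, ZP3 by 0.99±0.26 and FAM167A by 0.82±0.12. The readthrough gene MSH5-SAPCD1 (0.92±0.28) shares reads with MSH5 and is uncertain. The stem-cell receptor LGR6 went from 5.99±0.578 CPM to 1.51±0.246 CPM (-1.98±0.19, edgeR adjusted p = 1.5e-09). Others among the lowest were BMF, a pro-apoptotic BH3 gene (-1.41±0.18), FAM13B (-1.33±0.13), the integrin ITGB8 (-1.28±0.13), the serotonin receptor HTR2A (-1.20±0.12), VAV3 (-1.02±0.15) and EPHA3 (-0.99±0.13).

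Mitosis genes moved up (9 up and 0 down of 30, 11 and 0 adjusted over the list alone, median 0.16, camera adjusted p = 8.07e-07, adjusted p = 0.0165 with an estimated correlation), with CCNA2 at 0.29±0.07 and AURKB at 0.41±0.10. Cholesterol synthesis and uptake moved down (0 up and 5 down of 24, 0 and 8 adjusted over the list alone, median -0.12, camera adjusted p = 5.31e-05, adjusted p = 0.00695 with an estimated correlation). Its member LSS stood at -0.41±0.07. The other 12 list calls were lost with an estimated correlation. Up were NF-kB and inflammatory genes (7 up and 0 down of 30, 11 and 1 adjusted over the list alone), AhR targets (2 and 0 of 8, then 2 and 0), NRF2 targets (3 and 0 of 29, then 4 and 0), ATF4 targets (2 and 0 of 25, then 3 and 0), heat shock genes (3 and 0 of 18, then 3 and 0) and glucocorticoid-induced genes (1 and 0 of 8, then 2 and 0). ALDH1A3 stood at 0.73±0.05 and STIP1 at 0.25±0.04. Down were DNA replication genes (0 up and 6 down of 31, 0 and 6 adjusted over the list alone), neuron markers (0 and 3 of 7, then 0 and 3), extracellular matrix genes (0 and 3 of 26, then 0 and 3), lysosome and autophagy genes (1 and 3 of 23, then 1 and 3), fatty acid synthesis (1 and 3 of 13, then 1 and 3) and interferon-stimulated genes (0 and 2 of 26, then 0 and 4). CCNE2 stood at -0.51±0.09, MAP2 at -1.12±0.16 and SYT1 at -0.58±0.10. These had camera adjusted p between 1.17e-05 and 0.0352, and adjusted p between 0.0667 and 0.460 with an estimated correlation. With a library batch term, camera's adjusted p rose to 0.0704 for fatty acid synthesis, 0.0598 for interferon-stimulated genes and 0.0828 for heat shock genes.

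edgeR called 1197 genes, 589 up and 608 down. Leaving out vehicle replicates 1, 2 and 3 gave 938, 676 and 688, and leaving out Saengmaek-san replicates 1, 2 and 3 gave 932, 794 and 730. The early libraries alone (2 of Saengmaek-san per dose) gave 203 and the fit without the deviant library gave 2445.

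Guibi-tang at 500 µg/mL had the most genes called against vehicle, though fitted to the 6 libraries compared alone it had 4758 and Soyo-san 5990. Of the NF-kB and inflammatory genes 28 rose, 1 fell and 1 was not called (28 up and 1 down of 30, 28 and 2 adjusted over the list alone, median 2.69, camera adjusted p = 1.16e-36, adjusted p = 3.22e-07 with an estimated correlation). CXCL8 went from 3.07±0.583 CPM to 188±51.8 CPM (5.94±0.21, edgeR adjusted p = 1.9e-25). The neutrophil growth factor CSF3 rose by 6.38±0.37, the neutrophil chemokines CXCL1 by 5.50±0.35, CXCL2 by 5.48±0.30, CXCL3 by 4.25±0.29 and CXCL5 by 4.19±0.26. The adhesion molecule ICAM1 rose by 3.11±0.10, the cytokine IL6 by 3.64±0.17, the mitochondrial superoxide dismutase SOD2 by 3.21±0.10 and GDF15, a stress cytokine, by 4.43±0.33. HMOX1, the inducible heme oxygenase (ENSG00000100292, chromosome 22, 35380361 to 35394214, plus strand), went from 56.1±4.47 CPM to 850±385 CPM (3.92±0.16, edgeR adjusted p = 9.1e-24). Fibrillar collagen fell, with COL1A2 (ENSG00000164692, chromosome 7, 94394561 to 94431232, plus strand) going from 1785±55.1 CPM to 470±132 CPM (-1.93±0.12, edgeR adjusted p = 5.2e-17) and COL3A1 at -1.92±0.13. The lowest named genes were LGR6 (-4.07±0.25), PADI2 (-2.99±0.19), the integrin ITGB4 (-2.64±0.18), HMCN1 (-2.58±0.30), the clock-related factor HLF (-2.48±0.16), COL14A1 (-2.39±0.20) and the sodium channel SCN3A (-2.37±0.20). EIF3CL, which shares reads with its near copy EIF3C and is uncertain, was listed at 0 CPM against 5.52 CPM in vehicle and is given no fold.

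NRF2 targets (17 up and 4 down of 29, 18 and 4 adjusted over the list alone, camera adjusted p = 8.19e-10, adjusted p = 0.0198 with an estimated correlation) moved up with TXNRD1 (1.21±0.07), OSGIN1 (2.10±0.13) and SRXN1 (1.0±0.06). Lysosome and autophagy genes (15 up and 3 down of 23, 15 and 3 adjusted over the list alone, camera adjusted p = 1.64e-06, adjusted p = 0.0108 with an estimated correlation) moved up with the autophagy receptor SQSTM1 (2.13±0.10) and GPNMB (1.39±0.10). Interferon-stimulated genes (22 up and 0 down of 26, 22 and 0 adjusted over the list alone, camera adjusted p = 3.90e-14, adjusted p = 0.0198 with an estimated correlation) moved up with IFIT2 (2.58±0.16) and IFIT3 (2.20±0.12). Extracellular matrix genes (0 up and 25 down of 26, 0 and 25 adjusted over the list alone, camera adjusted p = 1.89e-21, adjusted p = 0.0198 with an estimated correlation) moved down. TGFBI stood at -0.82±0.06 and SPARC at -0.74±0.06. Unfolded protein response chaperones (2 up and 9 down of 18, 2 and 11 adjusted over the list alone, camera adjusted p = 5.22e-05, adjusted p = 0.0108 with an estimated correlation) moved down too, with HSPA5 at -1.13±0.07 and HSP90B1 at -0.83±0.08.

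The other 10 list calls were lost with an estimated correlation. Down were fatty acid synthesis (0 up and 12 down of 13, 0 and 12 adjusted over the list alone), DNA replication genes (3 and 13 of 31, then 4 and 15), glycolysis enzymes (0 and 7 of 11, then 1 and 7), astrocyte and glioma markers (0 and 6 of 9, then 0 and 7) and epithelial markers (1 and 3 of 5, then 1 and 3). The citrate lyase ACLY stood at -0.73±0.08, MCM6 at -0.73±0.06, PKM at -0.52±0.06, NES at -1.20±0.14 and KRT18 at -1.58±0.14. Up were ATF4 targets (11 up and 4 down of 25, 11 and 5 adjusted over the list alone), p53 targets (11 and 4 of 24, then 11 and 5), heat shock genes (10 and 2 of 18, then 10 and 2), immediate early and MAPK output genes (10 and 4 of 23, then 11 and 4) and FOXO targets (7 and 0 of 13, then 7 and 2). PPP1R15A stood at 1.5±0.10, the death receptor FAS at 0.96±0.09, BAG3 at 0.63±0.07, HSPA1A, which shares reads with HSPA1B, at 1.01±0.09, JUN at 0.91±0.09 and IRS2 at 1.25±0.13, though EGR3 fell (-1.23±0.13). These had camera adjusted p between 1.74e-06 and 0.0410, and adjusted p between 0.0520 and 0.236 with an estimated correlation, and camera's adjusted p for p53 targets was 0.0730 without the deviant library in the fit. Camera did not call LXR targets (2 up and 3 down of 8, camera adjusted p = 0.859), endothelial markers (0 up and 1 down of 5, camera adjusted p = 0.361), oligodendrocyte markers (1 up and 1 down of 3, camera adjusted p = 0.859) and myeloid markers (1 up and 2 down of 4, camera adjusted p = 0.0940).

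edgeR called 6137 genes, 3007 up and 3130 down, of which 476 rose and 527 fell at least 2-fold. Leaving out 1 of the 6 libraries compared gave 4494 to 6209, and the fit without the deviant library gave 7630.

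Soyo-san at 500 µg/mL, a mixed prescription that holds mint herb among its constituents, was led by inflammatory genes. Of the NF-kB and inflammatory genes 29 rose, 0 fell and 1 was not called (29 up and 0 down of 30, 29 and 0 adjusted over the list alone, median 2.43, camera adjusted p = 1.04e-88, adjusted p = 2.49e-12 with an estimated correlation). CXCL8 went from 3.07±0.583 CPM to 143±3.84 CPM (5.55±0.21, edgeR adjusted p = 2.0e-24). IL6 (ENSG00000136244, chromosome 7, 22725884 to 22732002, plus strand) went from 3.59±0.343 CPM to 33.9±3.65 CPM (3.24±0.16, edgeR adjusted p = 1.1e-19). CXCL1 rose by 5.49±0.35, CSF3 by 5.07±0.38, CXCL2 by 4.55±0.30, CXCL3 by 4.24±0.29, CXCL5 by 3.27±0.27 and the early response gene IER3 by 3.01±0.19. SAMD11 (ENSG00000187634, chromosome 1, 923928 to 944581, plus strand) went from 129±5.27 CPM to 25.2±1.13 CPM (-2.36±0.10, edgeR adjusted p = 7.9e-22). The differentiation inhibitor ID2 stood at -1.80±0.16. Also among the lowest were LGR6 (-1.98±0.19), VAV3 (-1.65±0.16), LONRF2 (-1.61±0.21), IFITM10 (-1.58±0.15), BMF (-1.49±0.18) and HR (-1.48±0.13). Hypoxia genes moved down (0 up and 7 down of 27, 0 and 8 adjusted over the list alone, camera adjusted p = 0.00975, adjusted p = 0.0204 with an estimated correlation), with the oxygen sensor EGLN3 at -0.65±0.11.

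Up were interferon-stimulated genes (14 up and 0 down of 26, 17 and 0 adjusted over the list alone) and ATF4 targets (5 and 2 of 25, then 7 and 2), with MX1 at 1.35±0.24 and ATF3 at 0.68±0.14. Down were extracellular matrix genes (0 up and 10 down of 26, 0 and 11 adjusted over the list alone) and FOXO targets (1 and 5 of 13, then 1 and 6), with THBS2 at -0.64±0.10, FOXO1 at -0.84±0.13 and SESN3 at -1.01±0.16. These 4 had camera adjusted p between 2.26e-09 and 0.0344, and adjusted p between 0.146 and 0.565 with an estimated correlation, so each call was lost with it. With a library batch term the FOXO list had camera adjusted p = 0.0995.

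edgeR called 2170 genes, 1039 up and 1131 down, and with a library batch term 1141. The count was 1902, 1367 and 1309 with vehicle replicates 1, 2 and 3 left out and 1408, 1511 and 1508 with Soyo-san replicates 1, 2 and 3 left out. It was 4139 without the deviant library. All 3 Soyo-san libraries are late and vehicle was taken as early, so the batch term rests on Saengmaek-san and Guibi-tang.

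Okbyeongpung-san at 500 µg/mL, which holds Saposhnikovia root among its constituents, was also led by inflammatory genes. Of the NF-kB and inflammatory genes 28 rose, 0 fell and 2 were not called (28 up and 0 down of 30, 29 and 0 adjusted over the list alone, median 2.11, camera adjusted p = 6.53e-92, adjusted p = 1.46e-12 with an estimated correlation). CXCL8 went from 3.07±0.583 CPM to 124±5.87 CPM (5.34±0.21, edgeR adjusted p = 1.2e-23). CXCL1 rose by 4.95±0.36, CSF3 by 4.55±0.38, CXCL2 by 3.93±0.31, CXCL3 by 3.54±0.30 and CXCL5 by 3.31±0.27. IL6 rose by 3.15±0.16, IER3 by 2.7±0.19, ICAM1 by 2.34±0.10 and SOD2 by 2.01±0.09. EGR1, an immediate early factor (ENSG00000120738, chromosome 5, 138465490 to 138469315, plus strand), went from 149±8.02 CPM to 52.7±8.48 CPM (-1.5±0.34, edgeR adjusted p = 0.00323). Also among the lowest were LGR6 (-1.43±0.18), ITGB4 (-1.40±0.16), LONRF2 (-1.26±0.21), PADI2 (-1.26±0.16) and COL14A1 (-1.17±0.18). So were HMCN1 (-1.09±0.27, edgeR adjusted p = 0.436 with a batch term) and C4A (-1.15±0.20), which shares reads with C4B and is uncertain.

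The other 9 list calls were lost with an estimated correlation. Up were ATF4 targets (6 up and 0 down of 25, 9 and 1 adjusted over the list alone), interferon-stimulated genes (6 and 0 of 26, then 9 and 0), oxidative phosphorylation genes of mitochondrial DNA (0 and 0 of 13, then 10 and 0) and ribosomal protein genes (0 and 0 of 76, then 0 and 0), with STC2 at 0.46±0.08 and IFI6 at 1.08±0.27 (edgeR adjusted p = 0.512 with a batch term). Down were extracellular matrix genes (0 up and 4 down of 26, 0 and 7 adjusted over the list alone), FOXO targets (0 and 3 of 13, then 0 and 3), astrocyte and glioma markers (1 and 3 of 9, then 1 and 5), DNA replication genes (0 and 3 of 31, then 0 and 5) and fatty acid synthesis (0 and 1 of 13, then 0 and 1), with TXNIP at -0.87±0.11. These had camera adjusted p between 4.67e-05 and 0.0431, and adjusted p between 0.142 and 0.891 with an estimated correlation. With a batch term, camera's adjusted p was 0.840 for the mitochondrial DNA list, 0.476 for the ribosomal list and 0.489 for fatty acid synthesis.

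edgeR called 1259 genes, 666 up and 593 down, and 507 with a library batch term. Omitting vehicle replicates 1, 2 and 3 gave 1019, 621 and 660, and omitting Okbyeongpung-san replicates 1, 2 and 3 gave 824, 783 and 660. The count was 3383 without the deviant library, and these libraries too are all late.

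**Figure D2:**
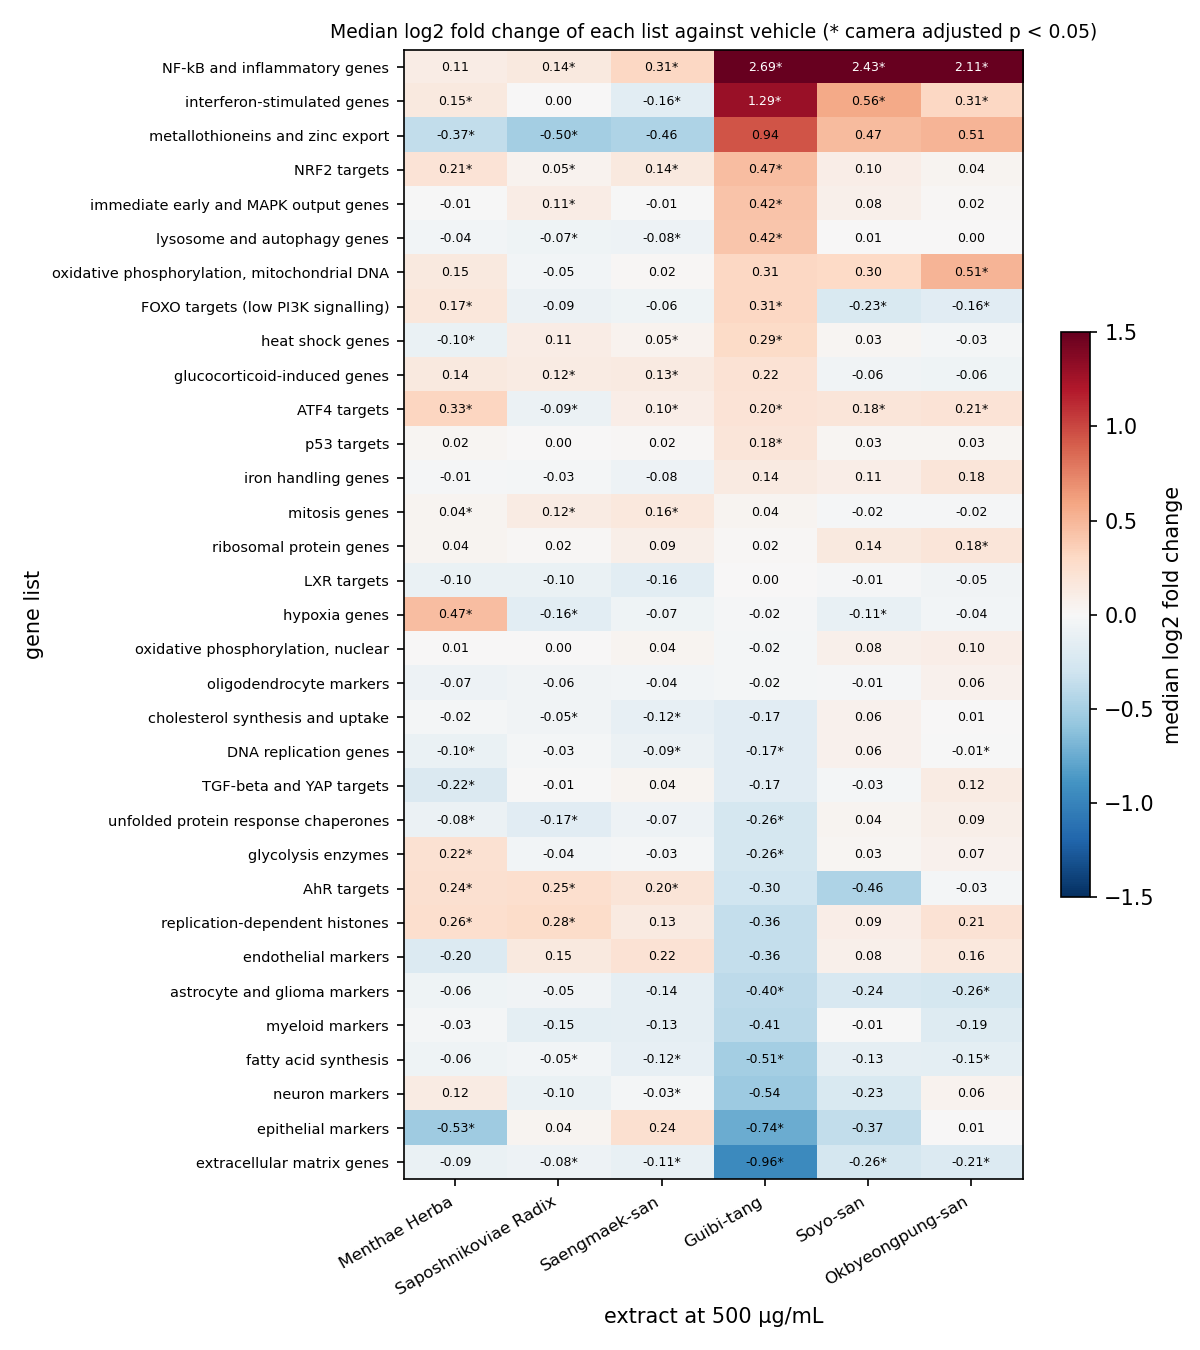
Median log2 fold change against vehicle of the members of each of the 33 lists for the 6 extracts at 500 µg/mL, with a star where camera's adjusted p was under 0.05 at the preset correlation. The NF-kB list stands at 2.69, 2.43 and 2.11 for Guibi-tang, Soyo-san and Okbyeongpung-san.

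**Figure D3:**
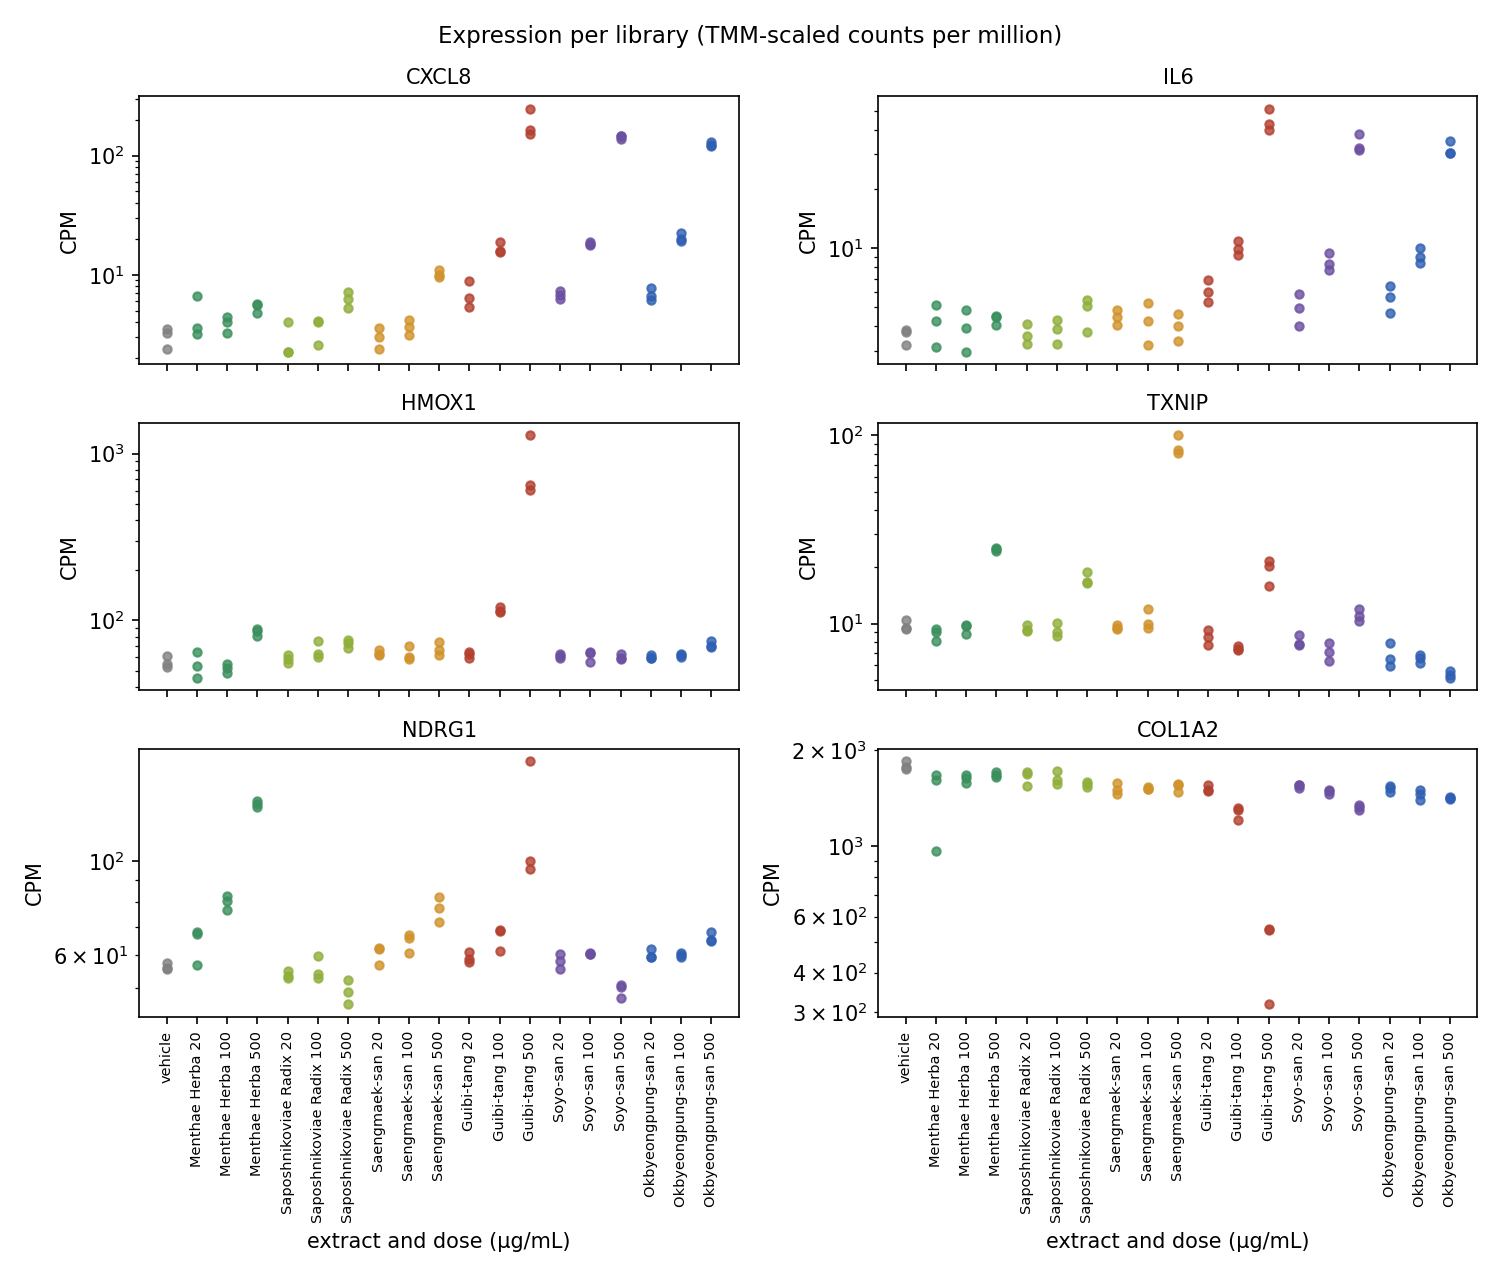
CPM (log axis) of 6 genes in each library, by extract and dose, 1 point per library and 3 per group. CXCL8 climbs from a vehicle mean of 3.07 CPM to 188 CPM with Guibi-tang at 500 µg/mL.

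At 100 µg/mL CXCL8 rose against vehicle by 2.45±0.21 with Guibi-tang, 2.57±0.21 with Soyo-san and 2.75±0.21 with Okbyeongpung-san. IL6 rose by 1.48±0.17, 1.24±0.17 and 1.35±0.17. Okbyeongpung-san also raised the cytokine IL32 (1.29±0.16), and Guibi-tang raised IGFN1 (1.40±0.26). KRTAP2-3 rose with Soyo-san (1.35±0.28), a call lost with a batch term (edgeR adjusted p = 0.340). PADI2 fell with all 3 (-1.5±0.16, -1.27±0.16 and -1.25±0.15), as did LGR6 (-1.78±0.19, -1.26±0.18 and -1.25±0.18). EGR1 fell with Guibi-tang (-1.29±0.34) and Okbyeongpung-san (-1.5±0.34). ZBED6, inside an intron of another gene and so uncertain, fell with Soyo-san (-1.24±0.36, edgeR adjusted p = 0.902 with a batch term). CCN1 rose with Menthae Herba (0.69±0.09), Saposhnikoviae Radix (0.54±0.09) and Saengmaek-san (0.54±0.09). Menthae Herba also raised APLN (0.81±0.14) and KLF7 (0.64±0.12) and lowered SLC7A8 (-0.96±0.18), PADI2 (-0.89±0.15) and SELENOW (-0.88±0.18). SHB rose with Saposhnikoviae Radix (0.31±0.06), tissue factor F3 (0.48±0.08) and the kinin receptor BDKRB1 (0.42±0.09, edgeR adjusted p = 0.0565 with a batch term) rose with Saengmaek-san, and PADI2 (-0.85±0.15) and PGM2L1 (-0.50±0.08) fell with it.

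edgeR called 18 up and 31 down with Menthae Herba at 100 µg/mL, 2 up and 0 down with Saposhnikoviae Radix (870 at an unadjusted p under 0.05, 2 up and 1 down by DESeq2) and 3 up and 3 down with Saengmaek-san. The Menthae Herba count was 16, 23 and 26 without vehicle replicates 1, 2 and 3 and 31, 13 and 21 without its own, and 92 without the deviant library. The Saposhnikoviae Radix count was 2, 0 and 0 without the vehicle replicates and 0, 1 and 1 without its own. Its zeros had 613, 585 and 412 genes in turn at edgeR's unadjusted p under 0.05. The Saengmaek-san count was 6, 4 and 2 and 4, 5 and 2 in the same order, 78 without the deviant library, and 0 by edgeR in the early libraries alone (664 at an unadjusted p under 0.05, with DESeq2 giving 27 in all libraries).

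Guibi-tang at 100 µg/mL had 193 up and 151 down, Soyo-san 222 up and 311 down and Okbyeongpung-san 72 up and 93 down by edgeR. Without vehicle replicates 1, 2 and 3 these counts were 222, 178 and 156 for Guibi-tang, 439, 176 and 152 for Soyo-san and 123, 80 and 62 for Okbyeongpung-san. Without the extract's replicates 1, 2 and 3 they were 321, 150 and 214, 289, 120 and 416 and 77, 89 and 89. A batch term gave 120 for Soyo-san and 99 for Okbyeongpung-san. Without the deviant library the 3 counts were 1152, 3163 and 1831.

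At 20 µg/mL CXCL8 rose by 1.18±0.22 with Guibi-tang, 1.15±0.22 with Soyo-san and 1.16±0.22 with Okbyeongpung-san. The NF-kB inhibitor NFKBIA rose by 0.67±0.11, 0.72±0.11 and 0.63±0.11. With a batch term the CXCL8 calls were lost, at edgeR adjusted p = 0.139, 0.156 and 0.119. So were those of NFKBIA, at edgeR adjusted p = 0.0576, 0.0563 and 0.0989. PADI2 fell with Guibi-tang (-0.79±0.15) and Soyo-san (-0.72±0.15), BDKRB1 rose with Guibi-tang (0.52±0.09), and MIR23AHG rose with Soyo-san (0.58±0.10) and Okbyeongpung-san (0.68±0.10). PGM2L1 fell with Saengmaek-san (-0.53±0.08), Soyo-san (-0.46±0.08) and Okbyeongpung-san (-0.39±0.08), and the stress gene SESN1 with Soyo-san (-0.48±0.09). Okbyeongpung-san lowered TXNIP (-0.53±0.11) and ZNF616 (-0.61±0.13). Saengmaek-san raised DBNDD2 (1.39±0.28), STX1A (0.38±0.07) and SHB (0.30±0.06) and lowered ARRDC3 (-0.39±0.07) and PPP4R2 (-0.30±0.06). Also lost with a batch term, by edgeR adjusted p, were the calls of BDKRB1 with Guibi-tang (0.0576), of MIR23AHG (0.0563), PGM2L1 (0.156) and SESN1 (0.156) with Soyo-san, of PGM2L1 (0.311) and ZNF616 (0.356) with Okbyeongpung-san, and of DBNDD2 (0.0605), STX1A (0.0605) and PPP4R2 (0.0647) with Saengmaek-san.

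edgeR called 0 genes with Saposhnikoviae Radix at 20 µg/mL (DESeq2 0), with 757 at an unadjusted p under 0.05, no excess over chance. It called 3 up and 3 down with Saengmaek-san. That count was 5, 1 and 1 without vehicle replicates 1, 2 and 3, 4, 1 and 10 without its own, 15 with the replicate number as a block, 3 with a batch term, 1 in the early libraries, 119 by DESeq2 and 847 with only the 6 libraries compared. Guibi-tang had 5 up and 2 down, with 2, 3 and 0 and 11, 0 and 5 in the same order, and 1 with a batch term. The zeros of Guibi-tang had 889 and 786 genes in turn at edgeR's unadjusted p under 0.05, against 24 calls by DESeq2 in all libraries.

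Soyo-san at 20 µg/mL had 8 up and 9 down by edgeR (10, 6 and 2 without vehicle replicates 1, 2 and 3, 0, 3 and 10 without its own, and 2 with a batch term). The 0 without its replicate 1 stood beside 1464 genes at an unadjusted p under 0.05 and 85 calls by DESeq2 in all libraries. Okbyeongpung-san had 20 up and 6 down (27, 4 and 5 and 9, 7 and 7, and 13 with a batch term). Without the deviant library in the fit the 20 µg/mL counts were 2 for Saposhnikoviae Radix, 358 for Saengmaek-san, 97 for Guibi-tang, 581 for Soyo-san and 753 for Okbyeongpung-san.

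Menthae Herba at 20 µg/mL had 1351 up and 273 down by edgeR, but replicate 2, the deviant library, stood apart from replicates 1 and 3 and decided this count. Short transcripts exceeded long ones in it by 1.02 on the log2 scale, against -0.47 to 0.33 in the other libraries, and mitochondrial transcripts took 6.27% of its counts. Without it edgeR called 0 genes, with 947 at an unadjusted p under 0.05. DESeq2 with it called 1680 up and 436 down. The count was 4894 without replicate 1, 7046 without replicate 3, and 21, 6 and 2 without vehicle replicates 1, 2 and 3. The non-coding RNA BCYRN1 (2.33±0.48), TMEM160 (1.99±0.34) and C4orf48 (1.81±0.33) were highest. C4A (-0.79±0.20), ISY1-RAB43 (-0.76±0.18) and BMF (-0.73±0.18) were lowest, and none of these 6 was called without that library, with BCYRN1 at 0.15.

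**Figure D4:**
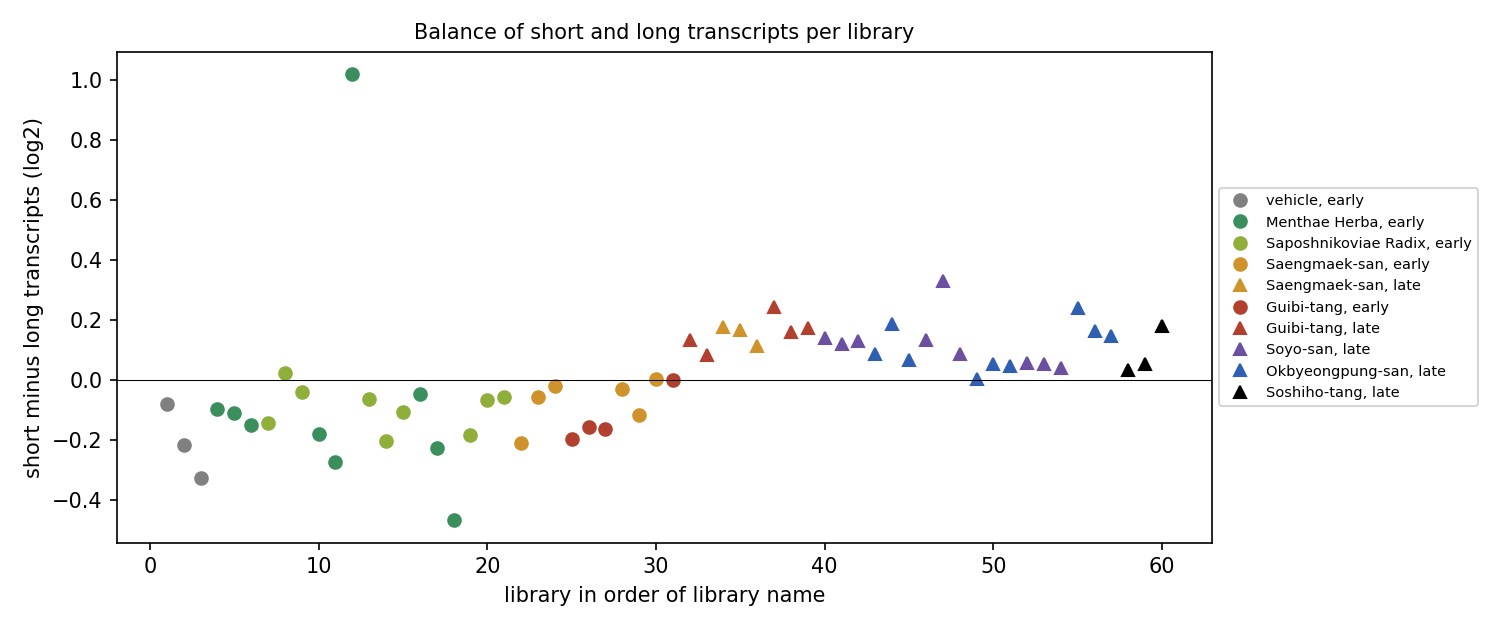
Mean log2 level of short transcripts minus that of long transcripts, relative to the other libraries, in each library in the order of library names, with triangles for late libraries. Menthae Herba 20 µg/mL replicate 2 stands at 1.02, above all other libraries, which lie between -0.47 and 0.33.

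Comparing 500 with 20 µg/mL of the same extract uses no vehicle library, and every such pair but those of Saengmaek-san and Guibi-tang lies in 1 part of the library order. With Guibi-tang, CSF3 rose by 5.91±0.35, CXCL2 by 4.81±0.28, CXCL8 by 4.76±0.19 (edgeR adjusted p = 2.3e-23), GDF15 by 4.45±0.32 and CXCL1 by 4.32±0.31. PADI2 (-2.20±0.19), ITGB4 (-2.18±0.18), HLF (-2.11±0.17), SCN3A (-2.10±0.20) and COL21A1 (-2.08±0.15) fell. NF-kB and inflammatory genes (28 up and 1 down of 30, 28 and 2 adjusted over the list alone, camera adjusted p = 1.68e-34, adjusted p = 6.37e-07 with an estimated correlation), NRF2 targets (17 up and 3 down of 29, 17 and 3 adjusted over the list alone, camera adjusted p = 1.80e-10, adjusted p = 0.0185 with an estimated correlation) and lysosome and autophagy genes (15 up and 2 down of 23, 15 and 2 adjusted over the list alone, camera adjusted p = 8.64e-07, adjusted p = 0.00913 with an estimated correlation) moved up. Extracellular matrix genes (0 up and 24 down of 26, 0 and 24 adjusted over the list alone, camera adjusted p = 5.61e-20, adjusted p = 0.0265 with an estimated correlation) moved down. Iron handling genes, for which the ferritins FTH1 (1.5±0.14) and FTL (1.44±0.18) rose and the transferrin receptor TFRC (-1.0±0.11) fell, were called up but not with an estimated correlation (5 up and 3 down of 10, 6 and 3 adjusted over the list alone, camera adjusted p = 0.0195, adjusted p = 0.0939 with an estimated correlation). edgeR called 5738 genes, 2780 up and 2958 down, 3850 to 5952 without 1 of the 6 libraries compared and 7270 without the deviant library.

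Soyo-san raised CSF3 (4.60±0.34), CXCL8 (4.40±0.19, edgeR adjusted p = 2.2e-22), CXCL1 (4.31±0.30), CXCL2 (3.91±0.27) and CXCL3 (3.81±0.27) from 20 to 500 µg/mL. It lowered SAMD11 (-2.57±0.11), ID2 (-1.86±0.16), ID3 (-1.66±0.17), DOK7 (-1.54±0.11) and DLX2 (-1.52±0.12), the ID genes being targets of BMP signalling. Okbyeongpung-san raised the chemokine gene CXCL8 by 4.18±0.19 (edgeR adjusted p = 1.0e-20) and CSF3 by 4.05±0.36. It lowered ITGB4 (-1.09±0.16), SLC7A8 (-0.83±0.18), EGR3 (-0.74±0.13), VAV3 (-0.70±0.16) and COL14A1 (-0.69±0.18). NF-kB and inflammatory genes moved up with Soyo-san (29 up and 0 down of 30, 29 and 0 adjusted over the list alone, camera adjusted p = 8.41e-141, adjusted p = 1.68e-15 with an estimated correlation) and Okbyeongpung-san (28 up and 0 down of 30, 29 and 0 adjusted over the list alone, camera adjusted p = 2.91e-158, adjusted p = 2.39e-16 with an estimated correlation). Iron handling genes moved up with Okbyeongpung-san (2 up and 0 down of 10, 2 and 0 adjusted over the list alone, camera adjusted p = 0.00162, adjusted p = 0.0431 with an estimated correlation), with ACO1 at 0.31±0.05 and the metal carrier SLC39A14 at 0.50±0.08. edgeR called 743 genes, 396 up and 347 down for Soyo-san, and 525 to 556 without 1 of its 6 libraries. For Okbyeongpung-san it called 277 genes, 190 up and 87 down, and 184 without its 500 µg/mL replicate 2. Without the deviant library these were 1190 and 491.

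Saengmaek-san raised TXNIP (3.21±0.10, edgeR adjusted p = 4.9e-27), CXCL8 (1.75±0.21), ARRDC4 (1.31±0.12), the serpin SERPINB3 (1.18±0.18) and KRTAP2-3 (1.16±0.26) from 20 to 500 µg/mL. It lowered LGR6 (-1.72±0.19), FAM13B (-1.17±0.13), MAP2 (-0.99±0.16), ITGB8 (-0.90±0.13) and MT1E (-0.94±0.26), the last uncertain among its near-identical family. Mitosis genes (4 up and 0 down of 30, 5 and 0 adjusted over the list alone, camera adjusted p = 5.27e-06, adjusted p = 0.0302 with an estimated correlation) moved up and cholesterol synthesis and uptake (0 up and 4 down of 24, 0 and 5 adjusted over the list alone, camera adjusted p = 0.000368, adjusted p = 0.0167 with an estimated correlation) down. edgeR called 801 genes, 390 up and 411 down, 431, 437 and 619 without the 500 µg/mL replicates 1, 2 and 3 and 490, 400 and 527 without those at 20 µg/mL, 54 in early libraries alone and 1755 without the deviant library.

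Saposhnikoviae Radix raised CXCL8 (1.17±0.22, edgeR adjusted p = 0.00778), TXNIP (0.88±0.10), complement C5 (0.73±0.15), MIR100HG (0.63±0.08) and the cyclooxygenase PTGS2 (0.57±0.10). It lowered DHRS3 (-0.45±0.09), LZTS3 (-0.42±0.09), FLCN (-0.39±0.07), STX3 (-0.38±0.07) and HSPA5 (-0.37±0.07). Unfolded protein response chaperones (0 up and 2 down of 18, 0 and 4 adjusted over the list alone, camera adjusted p = 1.75e-07, adjusted p = 0.000483 with an estimated correlation), hypoxia genes (0 up and 1 down of 27, 0 and 3 adjusted over the list alone, camera adjusted p = 2.57e-05, adjusted p = 0.000480 with an estimated correlation) and ATF4 targets (0 up and 0 down of 25, 0 and 1 adjusted over the list alone, camera adjusted p = 4.22e-06, adjusted p = 0.0250 with an estimated correlation) moved down. edgeR called 25 genes, 15 up and 10 down, 11, 15 and 3 without the 500 µg/mL replicates 1, 2 and 3 and 2, 9 and 15 without those at 20 µg/mL and 83 without the deviant library.

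With Menthae Herba, TXNIP (1.5±0.10, edgeR adjusted p = 3.6e-14), APLN (1.42±0.14), PPFIA4 (1.09±0.18), NDRG1 (1.09±0.11) and FER1L4 (1.07±0.20) rose. ANKRD1 (-1.88±0.19), PAPPA-AS1 (-1.65±0.43), MANCR (-1.28±0.25), SELENOW (-1.17±0.18) and MT1E (-1.31±0.27) fell. Hypoxia genes moved up (20 up and 0 down of 27, 21 and 0 adjusted over the list alone, camera adjusted p = 6.31e-21, adjusted p = 2.82e-11 with an estimated correlation). Ribosomal protein genes (0 up and 36 down of 76, 0 and 59 adjusted over the list alone, camera adjusted p = 2.69e-07, adjusted p = 0.592 with an estimated correlation) and nuclear oxidative phosphorylation genes (0 up and 14 down of 32, 0 and 21 adjusted over the list alone, camera adjusted p = 7.95e-05, adjusted p = 0.550 with an estimated correlation) were called down. Without replicate 2 at 20 µg/mL, whose short transcripts stood high, both were called up instead at the preset correlation, the only one tried there, with camera adjusted p = 1.77e-11 and 0.000347. edgeR called 2965 genes, 987 up and 1978 down, and 968 without that library, 5100 and 6538 without replicates 1 and 3 at 20 µg/mL and 1654, 1627 and 1589 without those at 500 µg/mL.

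Extracts were also compared directly at 500 µg/mL. Menthae Herba stood above Saposhnikoviae Radix for APLN (2.00±0.14, edgeR adjusted p = 3.2e-14), MIR210HG (1.62±0.20), NDRG1 (1.47±0.11), ALDOC (1.44±0.12) and the carbonic anhydrase CA9 (1.38±0.16). It stood below for ANKRD1 (-1.68±0.19), UCA1 (-1.63±0.16), CYP24A1 (-1.39±0.11) and SAMD11 (-1.31±0.10). Soyo-san stood above Okbyeongpung-san for the GTPase RRAD (1.32±0.12, edgeR adjusted p = 1.9e-10), TXNIP (1.05±0.11), TRAF1 (0.67±0.12), ADAMTS6 (0.67±0.09) and PTX3 (0.66±0.11). It was below for SAMD11 (-2.33±0.10), ID2 (-1.85±0.16), ID3 (-1.74±0.17), UCA1 (-1.63±0.15) and ATOH8 (-1.58±0.09). Saengmaek-san stood above Guibi-tang for ITGB4 (2.60±0.18, edgeR adjusted p = 1.5e-15), TXNIP (2.21±0.10), PADI2 (2.18±0.19), HMCN1 (2.02±0.30) and the matrix glycoprotein TNC (1.95±0.20). It was lower for CSF3 (-6.38±0.36), CXCL2 (-4.80±0.28), GDF15 (-4.54±0.32), CXCL1 (-4.44±0.31) and IGFN1 (-4.27±0.26).

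edgeR called 357 genes, 179 up and 178 down for Menthae Herba against Saposhnikoviae Radix, 224, 229 and 219 without Menthae Herba replicates 1, 2 and 3 and 233, 241 and 220 without those of Saposhnikoviae Radix. For Soyo-san against Okbyeongpung-san it called 224 genes, 59 up and 165 down, 151, 140 and 147 without Soyo-san replicates 1, 2 and 3 and 145, 136 and 147 without those of Okbyeongpung-san. Saengmaek-san against Guibi-tang gave 5268 genes, 2744 up and 2524 down, 3726 to 5273 without 1 of the 6 libraries compared and 3154 in the early libraries (2 per extract). These counts were 698, 439 and 6774 without the deviant library in the fit.

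A prescription was also set against a herb that is one of its constituents. Soyo-san stood above Menthae Herba for CSF3 (5.21±0.39, edgeR adjusted p = 2.8e-14), CXCL1 (5.19±0.35), CXCL8 (4.75±0.20), CXCL3 (4.02±0.29) and CXCL2 (4.02±0.29). It stood lower for APLN (-1.56±0.13), VAV3 (-1.55±0.16), TCAF2 (-1.5±0.16), PPFIA4 (-1.5±0.18) and the aldo-keto reductase AKR1B10 (-1.5±0.20). Okbyeongpung-san stood above Saposhnikoviae Radix for CSF3 (5.01±0.40, edgeR adjusted p = 2.9e-13), CXCL8 (4.30±0.19), CXCL1 (4.17±0.32), CXCL2 (3.80±0.30) and CXCL3 (3.51±0.29). Lower were TXNIP (-1.70±0.11), ITGB4 (-1.15±0.16), EGR1 (-1.12±0.34), LONRF2 (-1.12±0.21) and AKR1B10 (-1.07±0.20). edgeR called 2468 genes, 1210 up and 1258 down for the former, 1724 to 1946 without 1 of the 6 libraries compared. It called 803 genes, 486 up and 317 down for the latter, 503, 493 and 434 without Okbyeongpung-san replicates 1, 2 and 3 and 501, 469 and 465 without those of Saposhnikoviae Radix. Late libraries were set against early ones in both. The counts were 4122 and 2164 without the deviant library, and a batch term gave 1595 and 349, with the EGR1 and LONRF2 calls lost (edgeR adjusted p = 0.119 and 0.0723).

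Genes changed the same way by all 6 extracts were counted at each dose. At 500 µg/mL there were 4: CXCL8 rose by 0.80 to 5.94, and RGMB, a BMP co-receptor, rose by 0.25 to 0.88. SYT12 fell, with folds between -2.29 and -0.67, and IL10 fell, with folds between -3.14 and -1.16, at low levels. The product of the shares called, for independent lists, was 4.87e-06 genes. Simulated unchanged groups sharing a vehicle, without batches, gave at most 0 in 8 simulations. The 3 vehicle libraries cannot be split, so part of the excess may come from them. Without vehicle replicates 1, 2 and 3 the count was 0, 1 and 0 by edgeR, and without the deviant library in the fit 14. CCN1 was the gene so called at 100 µg/mL, with folds between 0.43 and 0.69, a result lost with a batch term and without vehicle replicate 2 or 3. By edgeR 0 genes were so called at 20 µg/mL, where single extracts had 757 to 4982 genes at an unadjusted p under 0.05 and 0 to 2116 by DESeq2. From 20 to 500 µg/mL, with no shared libraries, PTGS2 rose by 0.33 to 1.5 and RGMB by 0.24 to 0.74 with every extract.

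Effects were also correlated across genes, which are not independent replicates, for the 15 pairs of extracts. For the change from 20 to 500 µg/mL, Pearson's r was 0.229 between Soyo-san and Okbyeongpung-san (jackknife SE 0.0607), 0.224 between Guibi-tang and Soyo-san (0.0602), 0.217 between Saposhnikoviae Radix and Saengmaek-san (0.0952) and 0.182 between Guibi-tang and Okbyeongpung-san (0.0613). Soyo-san and its constituent Menthae Herba had r = 0.0188 (0.0523, Spearman's rho -0.0724), and Okbyeongpung-san and its constituent Saposhnikoviae Radix r = -0.00479 (0.0488, rho 0.138). Among the 9737 genes with a mean of at least 10 CPM, 11 of the 15 values moved by over 1 SE: Soyo-san and Okbyeongpung-san had r = 0.714, Saposhnikoviae Radix and Saengmaek-san 0.582, Guibi-tang and Okbyeongpung-san 0.404, Guibi-tang and Soyo-san 0.372 and Okbyeongpung-san and Saposhnikoviae Radix 0.264. Against vehicle at 500 µg/mL, Soyo-san and Okbyeongpung-san had r = 0.704 and a covariance of 0.170. They shared 479 genes up and 447 down, and 6 went opposite ways. Simulated unchanged groups sharing a vehicle, without batches, gave 0.524 and 0.0643. Independent lists would share 39.7 and 38.5, but a shared vehicle and, here, late libraries can also give common genes. This excess alone shows no shared response. Soyo-san and Menthae Herba had r = 0.414 against a simulated 0.525, a covariance of 0.0825 against 0.0665, 46 genes up and 94 down in both against 12.9 and 14.1, and 44 opposite. Okbyeongpung-san and Saposhnikoviae Radix had r = 0.457 against 0.515, a covariance of 0.0832 against 0.0662, 11 genes up and 3 down in both against 0.727 and 0.341, and 2 opposite.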

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

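Of the tests below, those of the length of transcripts in the deviant library, of the library batch and of myeloid cells for the NF-kB list, and of the vehicle libraries for the hypoxia list were chosen after seeing the result. The 5 comparisons between extracts at 500 µg/mL were set apart because the difference itself passed edgeR's test: 357 genes for Menthae Herba against Saposhnikoviae Radix, 5268 for Saengmaek-san against Guibi-tang, 224 for Soyo-san against Okbyeongpung-san, 2468 for Soyo-san against Menthae Herba and 803 for Okbyeongpung-san against Saposhnikoviae Radix.

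Late libraries of Saengmaek-san and Guibi-tang groups differed from early libraries of the same groups in 2361 genes, 1050 up and 1311 down, at a division found in the same data, and the term's correlation with log transcript length across genes was -0.457 (0.064 with GC). Oxidative phosphorylation genes of mitochondrial DNA had a median of 0.45 and ribosomal protein genes of 0.23. With every library thinned to 18.7 in units of 1e6 counts 1980 genes differed, so deeper sequencing of late libraries was not the whole source. The correlation, then -0.445, decides nothing, since thinning would keep it under any cause. Removing the trend with transcript length gave 1276 genes, 0.540 times the 2361 found first. A length bias of library preparation or RNA quality may account for part, and other sources stay open. The deviant library differed from its replicates with a correlation of -0.472 with log transcript length, as a length bias would give. With the length trend removed it correlated with the other groups' means at 0.970 at most, which a distorted library could give under any label, so a label exchange stays open, and no biological explanation was tested.

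NF-kB and inflammatory genes rose with Guibi-tang, Soyo-san and Okbyeongpung-san at 500 µg/mL. A difference between library batches is argued against by the median of 2.03 for Soyo-san at 500 against 20 µg/mL, late libraries alone. Myeloid cells are argued against too: 0 markers were called higher by edgeR with all 3 (adjusted p under 0.05; 4 of 10 were measured well enough to test, so the bound of 5 set for this test could not be reached, and 3 of 10 stood above 1 CPM here), and abundant myeloid transcripts were near 0 CPM, TYROBP at 0 in all 4 groups, LYZ at most 0.0320 and AIF1 at most 0.0259, while CD68, which these cells express, was 174 CPM in vehicle and 227, 223 and 206 CPM with the 3 extracts. Atractylodis Rhizoma, held by these 3 prescriptions and not by Soshiho-tang, was set against the Soshiho-tang library at 500 µg/mL, whose list median of 1.44 went against that herb as the whole cause, and a single library without replicates keeps it open. An effect of the 3 extracts stays a hypothesis, found and tested on the same data, and bacterial products in the extracts could give the same genes and were not tested.

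Hypoxia genes rose with Menthae Herba at 500 µg/mL. Vehicle libraries named apart from the others are argued against by the median of 0.59 against Saposhnikoviae Radix, which shares the early part of the library order, and a single library by the lowest median of 0.447 as each library was left out. Iron depletion by the extract would raise TFRC, the transferrin receptor, which was at -0.0135±0.11 (edgeR adjusted p = 0.990), so up to 0.206 at 2 SE, and this stays open because a small rise is not excluded. Low oxygen in the wells was not measured, and an effect of the extract may be the source, as a hypothesis.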

How the results depend on the processing

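The batch term, with its placing of vehicle, and the others so named above were chosen after seeing the data, and the rest before. edgeR's counts in all libraries, at 500, 100 and 20 µg/mL in this order throughout, were Menthae Herba 433, 49 and 1624, Saposhnikoviae Radix 29, 2 and 0, Saengmaek-san 1197, 6 and 6, Guibi-tang 6137, 344 and 7, Soyo-san 2170, 533 and 17 and Okbyeongpung-san 1259, 165 and 26 against vehicle. They were Menthae Herba 2965, Saposhnikoviae Radix 25, Saengmaek-san 801, Guibi-tang 5738, Soyo-san 743 and Okbyeongpung-san 277 from 20 to 500 µg/mL. Between extracts they were Menthae Herba against Saposhnikoviae Radix 357, Saengmaek-san against Guibi-tang 5268, Soyo-san against Okbyeongpung-san 224, Soyo-san against Menthae Herba 2468 and Okbyeongpung-san against Saposhnikoviae Radix 803. Counts that another setting moved by over 1.5 times follow. Where a setting changes the libraries or genes in the fit, the spread it estimates changes with it, and otherwise the cause was not tested.

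Leaving out 1 of the 6 libraries compared at a time gave, against vehicle, Menthae Herba 233 to 285, 13 to 31 and 0 to 7046, Saposhnikoviae Radix 8 to 10, 0 to 2 and 0 to 0, Saengmaek-san 676 to 938, 2 to 6 and 1 to 10, Guibi-tang 4494 to 6209, 150 to 321 and 0 to 11, Soyo-san 1309 to 1902, 120 to 439 and 0 to 10 and Okbyeongpung-san 621 to 1019, 62 to 123 and 4 to 27. From 20 to 500 µg/mL it gave Menthae Herba 968 to 6538, Saposhnikoviae Radix 2 to 15, Saengmaek-san 400 to 619, Guibi-tang 3850 to 5952, Soyo-san 525 to 556 and Okbyeongpung-san 184 to 207. Between extracts it gave Menthae Herba against Saposhnikoviae Radix 219 to 241, Saengmaek-san against Guibi-tang 3726 to 5273, Soyo-san against Okbyeongpung-san 136 to 151, Soyo-san against Menthae Herba 1724 to 1946 and Okbyeongpung-san against Saposhnikoviae Radix 434 to 503. Genes changed the same way by all 6 extracts numbered 4 and 1 against vehicle at 500 and 100 µg/mL, 0 to 1 and 0 to 1 as each vehicle library was left out, and 14 and 2 without the deviant library, with no other library left out.

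Without the filter on low counts edgeR gave against vehicle Menthae Herba 244 at 500 and 31 at 100, Saposhnikoviae Radix 11 at 500 and 1 at 100, Saengmaek-san 669 at 500 and 3 at 20, Guibi-tang 196 at 100, Soyo-san 334 at 100 and 8 at 20 and Okbyeongpung-san 837 at 500. The change from 20 to 500 µg/mL gave Saposhnikoviae Radix 8 and Saengmaek-san 292. Between extracts it gave Menthae Herba against Saposhnikoviae Radix 211 and Okbyeongpung-san against Saposhnikoviae Radix 510. With only the 6 libraries compared it gave against vehicle Menthae Herba 1257, 99 and 0, Saposhnikoviae Radix 98 at 500 and 8 at 20, Saengmaek-san 17 at 100 and 847 at 20, Guibi-tang 566 at 100 and 2 at 20, Soyo-san 5990, 3675 and 3731 and Okbyeongpung-san 4215, 3791 and 3164. Between 20 and 500 µg/mL it gave Menthae Herba 0, Saposhnikoviae Radix 42, Saengmaek-san 401, Guibi-tang 3519, Soyo-san 2633 and Okbyeongpung-san 516. For pairs of extracts it gave Menthae Herba against Saposhnikoviae Radix 966, Saengmaek-san against Guibi-tang 3041, Soyo-san against Okbyeongpung-san 642, Soyo-san against Menthae Herba 6221 and Okbyeongpung-san against Saposhnikoviae Radix 3143. Its counts of 0 stood beside 224 and 697 genes at an unadjusted p under 0.05. DESeq2 gave against vehicle Saposhnikoviae Radix 48 at 500, Saengmaek-san 27 at 100 and 119 at 20, Guibi-tang 24 at 20, Soyo-san 890 at 100 and 85 at 20 and Okbyeongpung-san 297 at 100 and 109 at 20. For 500 against 20 µg/mL it gave Saposhnikoviae Radix 48.

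Without the deviant library edgeR gave against vehicle Menthae Herba 937, 92 and 0, Saposhnikoviae Radix 97, 6 and 2, Saengmaek-san 2445, 78 and 358, Guibi-tang 1152 at 100 and 97 at 20, Soyo-san 4139, 3163 and 581 and Okbyeongpung-san 3383, 1831 and 753. The change from 20 to 500 µg/mL gave Menthae Herba 968, Saposhnikoviae Radix 83, Saengmaek-san 1755, Soyo-san 1190 and Okbyeongpung-san 491. Pairs of extracts had Menthae Herba against Saposhnikoviae Radix 698, Soyo-san against Okbyeongpung-san 439, Soyo-san against Menthae Herba 4122 and Okbyeongpung-san against Saposhnikoviae Radix 2164. Its count of 0 stood beside 947 genes at an unadjusted p under 0.05. With a library batch term as well it gave against vehicle Menthae Herba 1223, 123 and 4, Saposhnikoviae Radix 192, 6 and 4, Saengmaek-san 2532, 60 and 167, Guibi-tang 660 at 100 and 13 at 20, Soyo-san 326 at 100 and 52 at 20 and Okbyeongpung-san 257 at 100 and 76 at 20. Between 20 and 500 µg/mL it gave Menthae Herba 1549, Saposhnikoviae Radix 134, Saengmaek-san 2325, Soyo-san 1478 and Okbyeongpung-san 640. Between extracts it gave Menthae Herba against Saposhnikoviae Radix 944 and Soyo-san against Okbyeongpung-san 583. There were then 21 genes changed the same way by all 6 extracts, against 4. The batch term alone gave against vehicle Saengmaek-san 3 at 20, Guibi-tang 1 at 20, Soyo-san 1141, 120 and 2 and Okbyeongpung-san 507, 99 and 13. For pairs of extracts it gave Soyo-san against Menthae Herba 1595 and Okbyeongpung-san against Saposhnikoviae Radix 349. With the length trend removed edgeR gave against vehicle Saposhnikoviae Radix 61 at 500 and 5 at 100, Saengmaek-san 16 at 100 and 22 at 20, Guibi-tang 13 at 20 and Okbyeongpung-san 42 at 20. For 500 against 20 µg/mL it gave Saposhnikoviae Radix 49 and Saengmaek-san 1242. Pairs of extracts had Soyo-san against Okbyeongpung-san 339. Early libraries alone (2 of Saengmaek-san per dose, and of Guibi-tang 2, but only 1 at 100 and at 20 µg/mL) gave against vehicle Saengmaek-san 203, 0 and 1 and Guibi-tang 18 at 100 and 0 at 20. The change from 20 to 500 µg/mL gave Saengmaek-san 54 and Guibi-tang 2277. Between extracts it gave Saengmaek-san against Guibi-tang 3154. These counts of 0 stood beside 664 and 309 genes at an unadjusted p under 0.05. RLE scaling moved none of the 29 counts of single comparisons, gave 3 up and 5 down against 3 and 3 for Saengmaek-san at 20 µg/mL, and gave 2 genes changed the same way by all 6 extracts at 500 µg/mL.

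Lists called by camera fell, with an estimated correlation, from 15 to 8 for Menthae Herba, from 15 to 8 for Saposhnikoviae Radix, from 14 to 2 for Saengmaek-san, from 16 to 6 for Guibi-tang, from 6 to 2 for Soyo-san and from 10 to 1 for Okbyeongpung-san against vehicle at 500 µg/mL. From 20 to 500 µg/mL they fell from 16 to 1 for Menthae Herba, from 13 to 6 for Saposhnikoviae Radix, from 11 to 2 for Saengmaek-san, from 19 to 8 for Guibi-tang, from 7 to 1 for Soyo-san and from 5 to 2 for Okbyeongpung-san. Limma's fry, which asks another question, called 8 for Saposhnikoviae Radix, 26 for Guibi-tang, 13 for Soyo-san and 5 for Okbyeongpung-san against vehicle, and 6 for Saposhnikoviae Radix from 20 to 500 µg/mL. Of 147 list calls, 47 held with an estimated correlation, 113 with fry, 139 with the batch term, 139 without the deviant library and 147 with the replicate block.

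Reversals were seen in Menthae Herba at 500 against 20 µg/mL alone. Without replicate 2 at 20 µg/mL, log2 fold changes that were below 0 became 0.018 for MT2A, 0.0042 for NDUFS3, 0.0031 for SDHB, 0.11 for RPL9, 0.13 for RPL13A, 0.26 for RPL39 and 0.17 for RPS27A. With the batch term as well they were 0.018, 0.0046, 0.0035, 0.11, 0.13, 0.26 and 0.17 in the same order. Leaving out each library in turn, these folds ran from -1.11, -1.12, -0.84, -1.49, -1.35, -1.62 and -1.48 in that order up to the first values given. Both lists that reversed, with camera adjusted p = 0.000347 for nuclear oxidative phosphorylation and 1.77e-11 for ribosomal protein genes at the preset correlation, hold short transcripts, high in the library left out. Of the values of named genes, called or not, DESeq2 left 803 as they were and added 15 calls, and the batch term left 761 with 44 calls lost, 11 gained and 2 moved. Calls lost and gained were 103 and 63 with only the 6 libraries compared, 88 and 6 without the filter, 31 and 59 without the deviant library, 27 and 31 with the length trend removed and 4 and 4 with RLE scaling. Early libraries alone left 215 with 96 lost, and late ones 76 with 7 lost. Leaving out 1 of the compared libraries left 4298 values, with 593 calls lost, 9 gained, 7 reversed and 1 moved. Correlations of dose effects moved by over 1 jackknife SE in 11 of 15 pairs among genes of at least 10 CPM and in 8 with Spearman's rho. They moved from 0.0188 to -0.0724 with rho for Menthae Herba and Soyo-san, and from -0.00479 to 0.138 with rho and 0.264 among genes of at least 10 CPM for Saposhnikoviae Radix and Okbyeongpung-san.

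With the replicate number as a block, Saengmaek-san at 20 µg/mL against vehicle gave 15 genes instead of 6, and no other count moved by over 1.5 times. Same-numbered libraries deviated together, at r over 0.1 for every number, in 0 of 29 comparisons, and every library correlated best with its own number in the comparisons of 500 with 20 µg/mL of Saengmaek-san and Okbyeongpung-san alone, a hint from the data.

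The 6 libraries of each comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. In 24 comparisons 1 split of 10, the real one, gave as many genes. Real counts, fitted to those 6 libraries, and the highest of the other splits were, against vehicle, Menthae Herba 1257 and 1, 99 and 3, and 0 and 0. Saposhnikoviae Radix had 98 and 16, 3 and 3, and 8 and 8. Saengmaek-san had 1465 and 1, 17 and 0, and 847 and 2. Guibi-tang had 4758 and 0, 566 and 1, and 2 and 351. Soyo-san had 5990 and 0, 3675 and 0, and 3731 and 0. Okbyeongpung-san had 4215 and 0, 3791 and 0, and 3164 and 0. From 20 to 500 µg/mL they were Menthae Herba 0 and 0, Saposhnikoviae Radix 42 and 4, Saengmaek-san 401 and 1, Guibi-tang 3519 and 0, Soyo-san 2633 and 0, Okbyeongpung-san 516 and 1. Between extracts they were Menthae Herba against Saposhnikoviae Radix 966 and 1, Saengmaek-san against Guibi-tang 3041 and 0, Soyo-san against Okbyeongpung-san 642 and 1, Soyo-san against Menthae Herba 6221 and 0, Okbyeongpung-san against Saposhnikoviae Radix 3143 and 1. As many genes came from 10 splits for Menthae Herba at 20 µg/mL and for its 500 against 20 µg/mL, 5 for Saposhnikoviae Radix at 100 µg/mL, 2 at 20 µg/mL and 2 for Guibi-tang at 20 µg/mL. The Guibi-tang split with 351 genes sets vehicle replicate 1 and Guibi-tang replicates 2 and 3 against the rest, so both late libraries lie on 1 side, which may point to a structure of the samples, and the batch term gave 1 gene there.

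edgeR recovered 100 of 100 genes simulated at a log2 change of 1 over Guibi-tang and vehicle libraries and called 10 unchanged ones. Only genes of at least 5 CPM in vehicle were changed. Unchanged groups in 8 simulations, without batches, gave 0 or 1 calls against vehicle.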

Other observations

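All values for Soshiho-tang are of 1 library per dose with no replicate check. These libraries are late and vehicle was taken as early, so each ratio carries the batch difference. Early and late parts were found in the same data. The test for the herb held by other prescriptions was chosen before its result was seen. At 500 µg/mL CXCL8 stood at 77.6 CPM against 3.08 CPM in vehicle, a log2 ratio of 4.27, with 0.65 at 100 and 0.57 at 20 µg/mL. CXCL2 stood at 3.47, GDF15 at 3.27, HMOX1 at 3.22 (534 CPM) and TRIB3 at 3.03. Among the lowest were VAV3 at -2.34, PADI2 at -1.96, LYPD1 at -1.93 and ID2 at -1.91. Low levels depend on the pseudocount: with 0.5 and 5 CPM in place of 1, CXCL2 stood at 4.00 and 1.92, VAV3 at -2.57 and -1.40 and PADI2 at -2.18 and -1.11, while HMOX1 stood at 3.23 and 3.14.

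NF-kB and inflammatory genes in that library had a median of 1.44, above 0 in 29 of 30, and 0.17 at 100 µg/mL. ATF4 targets had 1.35 (25 of 25 above 0), immediate early and MAPK output genes 0.60, NRF2 targets 0.46 (27 of 29), cholesterol synthesis and uptake 0.46 (24 of 24) and fatty acid synthesis 0.35, each at percentile 100 of 10000 random lists. Extracellular matrix genes had -0.50, AhR targets -0.43, replication-dependent histones -0.42, hypoxia genes -0.35 and mitosis genes -0.24, each at percentile 0. Lower doses held some of these: AhR targets had -0.65 at 100 and -0.42 at 20 µg/mL (percentiles 0 and 0.01), and extracellular matrix genes -0.20 and -0.21 (both 0). Ribosomal protein genes, a list that was higher in late libraries, had 0.14, 0.14 and 0.22 at 500, 100 and 20 µg/mL, each at percentile 100.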
